A study of Mus musculus with 12 samples.

How the data were processed

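Poly(A) RNA from 12 cultures of CD1 mouse subventricular zone cells was sequenced with a stranded kit, per the labels. The table used here holds read counts per gene as deposited, with no normalization, and the 12 libraries were kept as separate columns. Per the submitters' processing notes, FastQC, STAR and featureCounts 1.22.2 were used with the GRCm38 build, while the order and settings of these steps, the annotation release, and the treatment of strand and of reads that map to several genes were not given in the sources used here. Genes that overlap or share long stretches with another gene are therefore uncertain. Of the genes named besides those marked in the text, Aldoa, Cacng4, Grin3a, Igf2bp3, Igf2r, Jun, Junb, Kif11, Lhfpl3, Mbp, Nkx6-2, Nrn1, Pfkp, Rps21, Slc30a10, Sox2, Srebf1, Timp3, Tmc3, Tnc and Veph1 overlap another gene, and Hist1h4i shares 28.9% of its stretches. The table lists 55401 Ensembl gene identifiers, of which 55141 were found in GENCODE release M21 of the mouse genome (54349 with the same version) and 260 were not, and the unmatched identifiers held 0.009% to 0.013% of the counts of a library. Coordinates and symbols come from that annotation on GRCm38. No count was recorded in any library for 24560 identifiers.

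Groups and replicate numbers were taken from the sample labels. The labels describe replicates from 4 independent litters and do not say whether the same number marks the same litter in different groups, so the number was not used as a block. Pairs of libraries in a group differed by more than sampling noise, with a chi-square per degree of freedom of at least 3.87, so that none was treated as a duplicate. The labels state 37 (in units of 1e6 reads) for each postnatal NSC library and 20 for the others, and all postnatal NSC totals were above the stated number. Any batch that followed the groups cannot be separated from the groups, and depth was made equal by thinning.

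Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and with Python 3.11.15. Genes were kept by filterByExpr by group (minimum count 10, minimum total 15), which left 16135, and were scaled by TMM. One edgeR quasi-likelihood fit with a term per group was made to all 12 libraries, with a common dispersion of 0.0513 (a biological coefficient of variation of 22.6%). The 3 contrasts were tested with two-sided tests, adjusted by Benjamini-Hochberg within each comparison and called at an adjusted p under 0.05. Gene lists of cell types and pathways with at least 4 tested members were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. Each list is also given as the number of members that rose or fell over all genes tested, and adjusted over the list alone. Since 45.1% to 53.1% of all genes tested were called in a comparison, such numbers alone do not set a list apart. Principal components used log2 CPM with a prior count of 2 over the 500 most variable genes.

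The groups, tests, gene lists, most alternatives and the rule for naming genes were chosen before the data were examined. The rule takes, per comparison, the 10 largest rises and the 10 largest falls among called genes with at least 5 CPM in the higher group and all 4 libraries of one group above all 4 of the other, passing over pseudogenes and genes without a descriptive symbol. A gene annotated as a pseudogene was among the 10 rises in OPC against adult NSC, since its symbol did not mark it, and it is not described. It adds 12 marker genes whatever their result, up to 4 members in each direction of a list the text describes, members that go against a list, and the highest marker of each other cell type. Where a group had no counts for a gene, a fold was computed against 3 counts over the group and is a lower bound. With 1 to 3 counts the ratio is given with a 95% interval from the exact binomial (Clopper-Pearson) distribution. These floors and intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

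The fit was tested on simulated counts with known changes in few genes, drawn from means without group differences. In the first comparison below, 66, 63 and 71 genes were changed 1.5-fold, 2-fold and 4-fold. In the data 45.1% to 53.1% of the genes tested were called. The simulation also gave all groups the same spread per gene. In the data, chi-square per degree of freedom between libraries was 3.87 to 9.88 within adult NSC. It was 6.31 to 92.56 within postnatal OPC and 54.33 to 206.62 within postnatal NSC. Recovery and false calls in the data may therefore differ from the simulated ones. For postnatal OPC against postnatal NSC (15889 genes), 21.2%, 58.7% and 85.9% of genes changed 1.5-fold, 2-fold and 4-fold were recovered, and 6 of 118 calls were false. For adult against postnatal NSC (15886 genes) the shares were 18.2%, 54.4% and 83.3%, with 2 of 102 calls false, and for postnatal OPC against adult NSC (15885 genes) they were 22.8%, 52.6% and 82.1%, with 10 of 118 calls false. The genes called in each comparison and the named genes were recomputed with other scaling (DESeq2 size factors, or library size alone), with DESeq2, without the filter, with a stricter filter (1 CPM in 4 libraries), with only the 8 libraries compared, with a replicate block, with all libraries thinned to the smallest total, and without each library in turn. Gene lists were tested again with an estimated correlation, with fry and with a replicate block, genes changed the same way with split controls and with thinning, and genes highest in 1 group with DESeq2 size factors and with a replicate block. Added after the data were seen were thinning for the gene lists and the removal of each library in turn for these 3 results. Added then as well were, for genes and gene lists, a covariate for Y-linked expression, for these and the other 2 results the removal of both libraries with low G1/S genes (postnatal NSC 3 and postnatal OPC 2), and for genes alone the removal of those sharing at least 50% of their 50-base stretches with another gene.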

Results

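RNA from cultured cells of the subventricular zone, the germinal layer that lines the lateral ventricles of the brain, was sequenced in 12 libraries from CD1 mice, 4 in each of 3 groups. Postnatal neural stem cell (NSC) libraries came from neurospheres, floating clusters of neural stem and progenitor cells, grown from pups of postnatal day 0 to 2. Adult NSC libraries came from neurospheres of animals aged 2 months, and postnatal oligodendrocyte precursor cell (OPC) libraries came from monolayers derived from postnatal neurospheres. Neurospheres were grown for 6 to 7 days with FGF at 10 ng/mL and EGF at 20 ng/mL, and OPC monolayers for 2 days with FGF and PDGF-AA, each at 10 ng/mL. The labels describe 4 independent litters as biological replicates. Total gene counts per library were 38928989 to 54801726 in postnatal NSC, 16756231 to 20064043 in adult NSC and 17226501 to 23651396 in postnatal OPC. Levels are given as CPM (counts per 1e6 of the normalised library size), mean ± SD of 4 libraries. Changes are given as log2 fold changes ± SE from one edgeR quasi-likelihood fit of 16135 genes in all 12 libraries, with Benjamini-Hochberg adjustment.

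The libraries separated by group, and the first principal component, 65.3% of the variance of the 500 most variable genes, set adult NSC apart from both postnatal groups. The median Spearman correlation across genes between libraries was 0.996 within adult NSC, 0.984 within postnatal OPC and 0.982 within postnatal NSC, against 0.945, 0.944 and 0.93 between groups, where genes are not independent replicates. Genes of DNA replication (G1/S list, 24 genes) were at a mean of 4.65 log2 CPM in postnatal NSC 3 and 4.26 in postnatal OPC 2, against 5.76 to 6.54 in the other 10 libraries. Xist, the RNA that silences an X chromosome in female cells, was at 870 CPM in postnatal NSC 2, 1375 CPM in postnatal NSC 3 and 1097 CPM in adult NSC 1. In these libraries the Y-linked gene Ddx3y was at 0.07 CPM or less. Both Xist and Ddx3y were measured in postnatal NSC 4 (554 and 16.4 CPM) and postnatal OPC 1 (989 and 19.6 CPM). The other 7 libraries had Ddx3y at 37.3 to 61.6 CPM with Xist at 0.53 CPM or less.

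**Figure D1:**
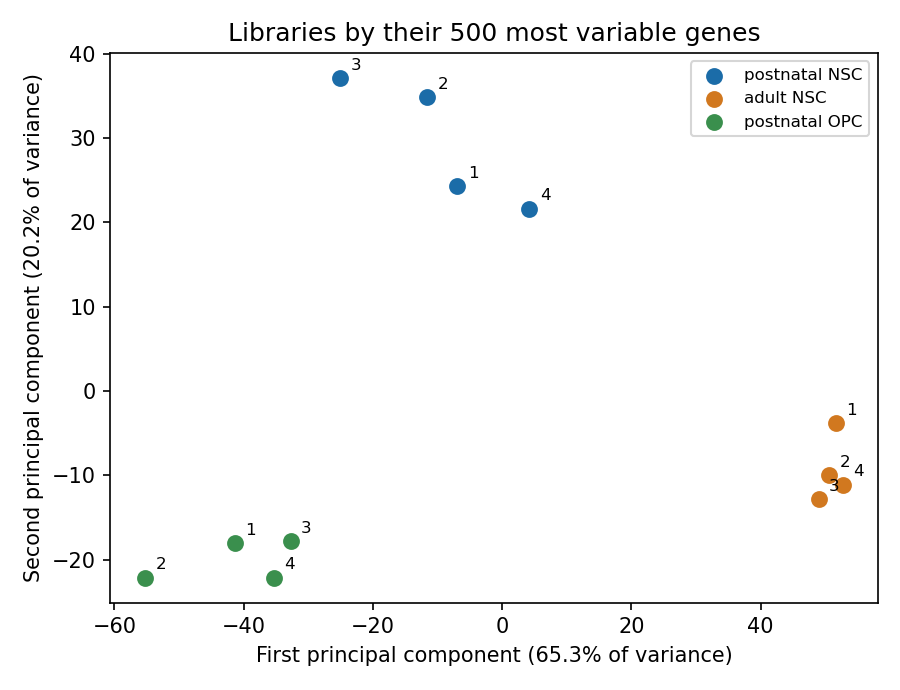
Each point is 1 of the 12 libraries, numbered by replicate and placed on the first (x axis, 65.3% of variance) and second (y axis, 20.2%) principal component of log2 CPM over the 500 most variable genes. The 4 adult NSC libraries lie between 49 and 52.7 on the first component, and all 8 postnatal libraries lie at 4.2 or below.

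Which transcripts distinguish OPC monolayers from the neurospheres of the same age was addressed by comparing postnatal OPC with postnatal NSC. Pdgfra, the receptor for the PDGF-AA added to OPC medium, was 6.23-fold higher in OPC (1433 ± 710 against 230 ± 59.6 CPM, n = 4 each). The gene Cspg4, which encodes the NG2 proteoglycan of OPC, was 2.57-fold higher (340 ± 44.6 against 132 ± 33.9 CPM). Among the named genes, the vesicle protein gene Rph3a had the largest rise (93.9 ± 20.7 against 5.02 ± 1.45 CPM, 18.7-fold). The sodium channel gene Scn3a rose 10.6-fold and the kainate receptor gene Grik1 8.29-fold. The largest fall was that of Fosb, an AP-1 transcription factor gene, from 1274 ± 872 CPM in postnatal NSC to 0.291 ± 0.133 CPM in OPC. Matrix genes fell too, such as Tnc, which encodes tenascin-C (1142 ± 668 to 45.3 ± 4.52 CPM, 25.2-fold lower). In all, 3614 of 16135 genes were higher and 3662 lower in OPC in edgeR's quasi-likelihood test, of which 1127 and 1566 changed by at least 1 on the log2 scale.

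Of the 24 tested genes of the oligodendrocyte precursor list, 15 rose, none fell and 9 did not pass the test, with 15 rising when adjusted over the list alone (camera adjusted p = 2.12e-08). With an estimated correlation the camera adjusted p of this list was 0.194. Cacng4, an AMPA receptor auxiliary subunit gene, rose by 1.84 ± 0.10 with an edgeR quasi-likelihood adjusted p of 3.44e-07. Lhfpl3 rose 6.31-fold (62.8 ± 16.9 to 396 ± 98.8 CPM), the neuroglycan gene Cspg5 2.53-fold and the phosphatase gene Ptprz1 1.71-fold. Olig2, a transcription factor gene of the oligodendrocyte lineage, rose by 0.77 ± 0.19. Its neighbour Olig1 (log2 fold change 0.41 ± 0.18, edgeR quasi-likelihood adjusted p = 0.081) and Sox10 (0.49 ± 0.43, edgeR quasi-likelihood adjusted p = 0.382) did not pass. Among 23 neurotransmitter receptor and ion channel genes, 15 rose and 4 fell, or 15 and 5 adjusted over the list alone (camera adjusted p = 2.44e-07, and 0.00713 with an estimated correlation). Besides Scn3a and Grik1, the AMPA receptor gene Gria2 rose 3.22-fold (145 ± 22.8 to 467 ± 54.1 CPM). The gene Gria1, which encodes another subunit of that receptor, fell 6.84-fold (9.63 ± 6.44 to 1.44 ± 0.917 CPM). Without postnatal NSC 4 the log2 fold change of Olig1 passed at 0.57 (edgeR quasi-likelihood adjusted p of 0.0129, and 0.0129 to 0.392 over all edgeR settings). With Y-linked expression as a covariate that of Olig2 was 0.62 (edgeR quasi-likelihood adjusted p of 0.0762, and 0.000701 to 0.0762 over all edgeR settings).

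Of 16 immediate early genes, which respond to a stimulus within minutes, 14 fell and none rose, and all 16 fell when adjusted over the list alone (camera adjusted p = 1.12e-19, but 0.111 with an estimated correlation). Fos fell from 1408 ± 840 to 8.64 ± 4.50 CPM, Junb from 315 ± 167 to 2.80 ± 0.865 CPM and Jun 11.7-fold. Without both libraries with low G1/S genes Fos fell by 6.58 in place of 7.36 on the log2 scale. Of 27 extracellular matrix and basement membrane genes, 24 fell and none rose, the same numbers as when adjusted over the list alone (camera adjusted p = 2.35e-18, and 0.0951 with an estimated correlation). Beside Tnc, the membrane protease gene Mmp14 fell by 2.19 ± 0.14, the thrombospondin gene Thbs2 by 5.70 ± 0.44 and the laminin gene Lama5 by 2.98 ± 0.25 on the log2 scale. Markers of pericytes and fibroblasts fell too, 5 of 6 tested and 5 adjusted over the list alone (camera adjusted p = 2.06e-05, and 0.111 with an estimated correlation). The collagen gene Col1a1 was at 9.75 ± 3.45 CPM in neurospheres and 0.345 ± 0.144 CPM in OPC.

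Genes of neural stem cells were mostly lower in OPC. In the neural stem and radial glia list, 12 of 18 genes fell and 3 rose, or 13 and 3 adjusted over the list alone (camera adjusted p = 0.014, and 0.545 with an estimated correlation). The intermediate filament genes Vim (2833 ± 416 to 864 ± 317 CPM) and Nes (1534 ± 134 to 745 ± 194 CPM) fell, while Fabp7, Sox2 and Sox9 rose by 0.89 ± 0.13, 0.73 ± 0.16 and 0.93 ± 0.23. Of 17 genes of quiescent adult neural stem cells, 8 fell and 2 rose, likewise adjusted over the list alone (camera adjusted p = 0.0108, and 0.57 with an estimated correlation). The receptor gene Notch3 fell 4.11-fold and the transcription factor gene Nfix 2.27-fold, while the glutamate transporter gene Slc1a2 rose 1.97-fold. The Notch pathway list had 7 falls and 1 rise among 14 genes, likewise adjusted over the list alone (camera adjusted p = 0.00767, and 0.545 with an estimated correlation). The Notch-modifying enzyme gene Lfng fell 2.64-fold. Without postnatal NSC 3, where G1/S genes were low, the camera adjusted p was 0.0802 for the quiescent list (0.000631 to 0.57 over all camera settings) and 0.0649 for the Notch list (0.000849 to 0.545). With Y-linked expression as a covariate it was 0.125 for the neural stem list (0.00463 to 0.545) and 0.0639 for the quiescent list, again by camera adjusted p. Gfap, an intermediate filament gene of astrocytes and neural stem cells, fell 5.29-fold (121 ± 93.9 to 22.9 ± 13.0 CPM) and Egfr, the receptor for the EGF in neurosphere medium, fell 1.71-fold. Both calls were lost with Y-linked expression as a covariate (edgeR quasi-likelihood adjusted p of 0.126 and 0.115, and 0.00206 to 0.126 and 8.07e-05 to 0.115 over all edgeR settings). Dcx, a microtubule-associated protein gene of neuroblasts, rose by 2.72 ± 0.52 on the log2 scale (12.2 ± 5.98 to 80.3 ± 57.9 CPM) and by 2.08 without postnatal OPC 2, while the interneuron transcription factor gene Dlx2 fell 3.33-fold. The 18 neuroblast and neuron genes split into 8 rises and 6 falls, or 8 and 7 adjusted over the list alone (camera adjusted p = 0.655). Their median log2 fold change was −0.21, but the camera direction was upward. Of 15 genes of mature oligodendrocytes and myelin, 3 rose and 5 fell, or 3 and 6 adjusted over the list alone (camera adjusted p = 0.562). Mbp, myelin basic protein, was at 7.85 ± 2.595 CPM in OPC and 23.3 ± 21.3 CPM in postnatal NSC (edgeR quasi-likelihood adjusted p = 0.0552). Without postnatal NSC 4 it fell by 1.98 on the log2 scale (edgeR quasi-likelihood adjusted p of 0.00265, and 0.00265 to 0.287 over all edgeR settings).

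Of 23 glycolysis and hypoxia genes, 18 fell and none rose, or 19 adjusted over the list alone (camera adjusted p = 2.06e-05, and 0.545 with an estimated correlation). The aldolase gene Aldoa fell 2.62-fold and the angiogenic factor gene Vegfa 4.59-fold. Nuclear genes of oxidative phosphorylation fell in 16 of 29 cases, also adjusted over the list alone (camera adjusted p = 0.00725, and 0.692 with an estimated correlation). Of 76 ribosomal protein genes, 35 fell, also adjusted over the list alone (camera adjusted p = 0.000205, and 0.769 with an estimated correlation). Rps21 was 1.9-fold lower. Of 18 unfolded protein and amino acid stress genes, 8 fell, likewise adjusted over the list alone (camera adjusted p = 0.00281, and 0.332 with an estimated correlation). The cystine transporter gene Slc7a11 fell 4.16-fold. Mitochondrially encoded genes rose, 12 of 18 with 1 fall, or 12 and 2 adjusted over the list alone (camera adjusted p = 0.00845, and 0.684 with an estimated correlation). Without postnatal NSC 2 the camera adjusted p was 0.0584 (0.000298 to 0.684 over all camera settings). The gene mt-Nd4l was at 536 ± 69.7 CPM in OPC and 277 ± 63.6 CPM in postnatal NSC, counts that are uncertain, since it overlaps mt-Nd4 and shares 98.8% of its stretches with other genes. Of 44 replication-dependent histone genes, whose transcripts mostly lack a poly(A) tail, 32 fell and none rose, or 35 adjusted over the list alone (camera adjusted p = 2.44e-07, and 0.449 with an estimated correlation). Many genes of this list share at least 50% of their stretches with other genes, so their counts are uncertain. The linker histone gene Hist1h1c fell 2.76-fold (142 ± 24.1 to 51.4 ± 10.5 CPM). Of 24 G1/S genes 1 rose by edgeR's quasi-likelihood test and 0 adjusted over the list alone (camera adjusted p = 0.562).

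Markers of other cell types were followed as well. The ependymal list fell in 4 of 5 genes, likewise adjusted over the list alone (camera adjusted p = 0.014, and 0.154 with an estimated correlation). Without both libraries with low G1/S genes this camera adjusted p was 0.0703 (0.00967 to 0.154 over all camera settings). The ciliary transcription factor gene Foxj1 was at 40.7 ± 5.60 CPM in postnatal NSC and 12.6 ± 3.09 CPM in OPC. The interferon and MHC class I list had 7 falls and 2 rises among 15 genes, or 7 and 3 adjusted over the list alone (camera adjusted p = 0.0196, and 0.449 with an estimated correlation). The camera adjusted p was 0.0608 without postnatal NSC 3, 0.0857 without that library and postnatal OPC 2, and 0.102 with Y-linked expression as a covariate (0.00967 to 0.449 over all camera settings). The MHC gene H2-K1 fell 2.56-fold. Among 5 endothelial genes, 2 fell and none rose, also adjusted over the list alone (camera adjusted p = 0.35). Flt1 was at 7.24 ± 4.88 CPM in postnatal NSC. Too few markers of microglia (2), choroid plexus (1) and erythroid cells (0) were tested for a list test. Otx2, counted with choroid plexus, was at 8.31 ± 2.17 CPM in postnatal NSC, 2.09 ± 0.981 CPM in adult NSC and 4.49 ± 1.41 CPM in OPC.

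The protein-coding gene Rph3a (ENSMUSG00000029608.10) lies on chromosome 5 from 120940499 to 121010092 (GRCm38), Scn3a (ENSMUSG00000057182.15) on chromosome 2 from 65457118 to 65567627, Fosb (ENSMUSG00000003545.3) on chromosome 7 from 19302696 to 19310051, and Pdgfra (ENSMUSG00000029231.15) on chromosome 5 from 75152292 to 75198215. The other large rises were those of the collagen gene Col19a1 (14.8-fold), Lrrn4 (11.6-fold), the integrin gene Itga8 (9.02-fold), Sorcs3 (8.83-fold) and the microRNA gene Mir703 (10.2-fold). So were those of the signal recognition particle RNA genes Rn7s1 and Rn7s2 (both 17.4-fold), a pair of near-identical copies whose counts are uncertain. The other large falls were those of Atf3 (388-fold), Egr4 (253-fold), the annexin gene Anxa3 (121-fold), Klf4 (99.4-fold), Klf2 (88.5-fold) and Zfp36 (79.9-fold). Prss22, with 1480 counts in postnatal NSC and none in OPC, was at least 236-fold lower. Without postnatal NSC 3, Atf3 fell by 7.83, Egr4 by 7.33, Klf4 by 6.05 and Klf2 by 5.39 on the log2 scale, in place of 8.60, 7.98, 6.64 and 6.47. Without postnatal OPC 2, the log2 fold change of Mki67, a proliferation marker gene, passed at 0.46 in place of 0.28 ± 0.21 (edgeR quasi-likelihood adjusted p of 0.00948 in place of 0.299, and 0.00217 to 0.554 over all edgeR settings).

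**Figure D2:**
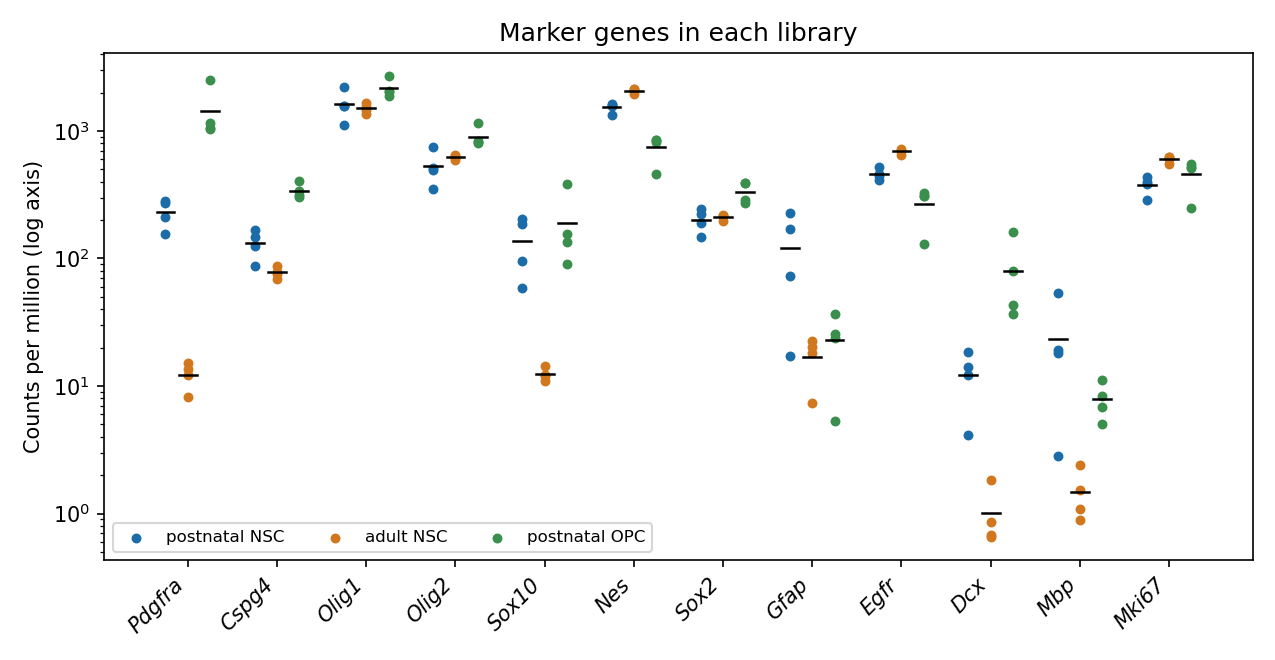
CPM (y axis, log scale) of 12 marker genes (x axis) in each library, with 1 point per library, a black line at the mean of the 4 libraries, and colours for postnatal NSC, adult NSC and postnatal OPC. Pdgfra averaged 1433 CPM in postnatal OPC, 230 CPM in postnatal NSC and 12.2 CPM in adult NSC.

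How neurosphere cells of different ages differ was addressed by comparing adult with postnatal NSC. Adult neurospheres had far less of the oligodendrocyte lineage receptor Pdgfra (12.2 ± 2.99 against 230 ± 59.6 CPM, 18.8-fold lower) and of the transcription factor gene Sox10 (12.4 ± 1.48 against 136 ± 70.3 CPM, 11-fold lower, n = 4 each). Olig1 and Olig2 differed by −0.10 ± 0.18 and 0.24 ± 0.19 on the log2 scale and did not pass. Olig2 passed without postnatal NSC 4 (0.42, edgeR quasi-likelihood adjusted p of 0.0413, and 0.0413 to 0.688 over all edgeR settings). The largest rise among the named genes was that of the small GTPase gene Rab26, at 83.9 ± 6.09 CPM in adult and 0.563 ± 0.325 CPM in postnatal neurospheres (146-fold). Rab3b, another small GTPase gene, was at 273 ± 25.3 and 13.0 ± 22.3 CPM (a log2 rise of 4.395, and of 7.11 without postnatal NSC 4). The stem cell filament gene Nes (1.35-fold), Egfr (1.5-fold) and Mki67 (1.59-fold) were higher in adult neurospheres, and Dcx was 12-fold lower. Cspg4 fell 1.7-fold, and Sox2 (213 ± 9.95 and 201.5 ± 42.7 CPM) did not pass the test. The calls for Nes and Egfr were lost when any 1 of the 8 libraries was left out (edgeR quasi-likelihood adjusted p of 0.06 to 0.0999 and 0.0539 to 0.0964, and 0.000295 to 0.0999 and 0.000123 to 0.0964 over all edgeR settings). For both genes all adult libraries were above all postnatal NSC libraries. The spread in this fit also drew on OPC, where postnatal OPC 2 lay far below the others. Its log2 CPM was 8.832 against 9.669 to 9.742 for Nes, and 7.011 against 8.276 to 8.351 for Egfr. In edgeR's quasi-likelihood test 4065 genes were higher and 4504 lower in adult NSC, of which 1060 and 2170 changed by at least 1 on the log2 scale.

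Of the 24 oligodendrocyte precursor genes, 19 fell and 2 rose in adult NSC, the same numbers as when adjusted over the list alone (camera adjusted p = 7.67e-08, but 0.688 with an estimated correlation). The matrilin gene Matn4 fell from 41.9 ± 15.9 to 0.231 ± 0.144 CPM and the proteoglycan genes Cspg5 and Bcan fell 3.16-fold and 4.17-fold. By contrast, Megf11 rose by 1.36 ± 0.18 and the xylosyltransferase gene Xylt1 by 0.83 ± 0.23. Of 17 genes of newly formed oligodendrocytes, 11 fell and 1 rose, likewise adjusted over the list alone (camera adjusted p = 0.0024, and 0.688 with an estimated correlation). Gpr17, a receptor gene of differentiating precursors, fell from 543 ± 408 to 4.93 ± 1.73 CPM. The mature oligodendrocyte and myelin list had 8 falls and 2 rises among 15 genes, also adjusted over the list alone (camera adjusted p = 0.194). Mbp fell by 3.97 ± 0.72 and by 3.17 without postnatal NSC 3, and the myelin gene Mobp rose 4.66-fold. Among 18 astrocyte genes, 10 fell and none rose, or 10 and 1 adjusted over the list alone (camera adjusted p = 0.00509, and 0.688 with an estimated correlation). The lipoprotein gene Apoe was 23.2-fold lower (811 ± 463 to 35.03 ± 4.43 CPM) and Gfap 7.12-fold lower. Of 17 genes of quiescent adult neural stem cells, 9 fell and 1 rose in the adult cultures, likewise adjusted over the list alone (camera adjusted p = 0.0134, and 0.688 with an estimated correlation). Without both libraries with low G1/S genes the camera adjusted p was 0.0547 (0.00064 to 0.688 over all camera settings). The adhesion molecule gene Vcam1 fell 6.4-fold and the neurotensin receptor gene Ntsr2, also in the astrocyte list, 8.32-fold.

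Of 24 G2/M cell cycle genes, 7 rose and none fell, or 6 adjusted over the list alone (camera adjusted p = 0.0419, and 0.749 with an estimated correlation). Over all 16135 genes tested, 4065 rose and 4504 fell, so the share of rises in this list was near that of all genes. The mitotic kinesin genes Kif20b and Kif11 rose 2.16-fold and 2.01-fold. Without postnatal NSC 3, where G1/S genes were low, the camera adjusted p of this list was 0.209, and it was 0.0543 with Y-linked expression as a covariate (0.0172 to 0.749 over all camera settings). Of 24 G1/S genes, 2 rose by edgeR's quasi-likelihood test and 0 adjusted over the list alone (camera adjusted p = 0.125). Immediate early genes fell in adult as in OPC libraries, 15 of 16 with none rising, likewise adjusted over the list alone (camera adjusted p = 6.43e-10, but 0.688 with an estimated correlation). Fosb was at 1.06 ± 0.285 CPM in adult NSC, and the nuclear receptor gene Nr4a1 fell from 496 ± 227 to 21.6 ± 1.72 CPM. Of 44 replication-dependent histone genes, 31 fell and 1 (Hist1h4i) rose, or 32 and 1 adjusted over the list alone (camera adjusted p = 4.73e-06, and 0.688 with an estimated correlation). Hist1h1c was 4.61-fold lower. Among 14 genes of transit-amplifying progenitors, the dividing cells that neural stem cells give rise to, 8 fell and 2 rose, also adjusted over the list alone (camera adjusted p = 0.0731). The Notch ligand gene Dll3 fell 17.7-fold and Sox11 rose 2.07-fold. Extracellular matrix genes went both ways, 8 up and 5 down of 27, also adjusted over the list alone (camera adjusted p = 0.38), and Tnc rose 3.42-fold. Of the 6 pericyte and fibroblast genes, 3 fell and none rose, or 4 adjusted over the list alone (camera adjusted p = 0.194).

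The protein-coding gene Rab26 (ENSMUSG00000079657.10) lies on chromosome 17 from 24527241 to 24534210 (GRCm38). It overlaps Rab26os on the other strand and Traf7 on its own, and the counting of such reads was not stated. Matn4 (ENSMUSG00000016995.17) lies on chromosome 2 from 164389393 to 164405160, Gpr17 (ENSMUSG00000052229.5) on chromosome 18 from 31942997 to 31949636, overlapping Lims2 on the other strand, and Sox10 (ENSMUSG00000033006.10) on chromosome 15 from 79154908 to 79165240. Further large rises were those of the channel-like gene Tmc3 (39.4-fold), C1qtnf1 (23-fold), the myosin gene Myo7a (22.7-fold), the neuritin gene Nrn1 (21.1-fold), the thrombomodulin gene Thbd (19.4-fold), Tm4sf1 (17.9-fold), Cpne8 (15.4-fold) and Stac2 (14.9-fold). Further large falls were those of the fatty acid hydroxylase gene Fa2h (114-fold), the zinc transporter family gene Slc30a10 (105-fold), the biglycan gene Bgn (91-fold) and Veph1 (90.7-fold). Bmp4 had 1 count in the adult libraries (ratio 634, 95% counting interval 114 to 25000), Prss22 had 2 (ratio 319, 88.1 to 2640) and P4ha3, a collagen hydroxylase subunit gene, had 3 (ratio 169, 57.8 to 822). Without postnatal NSC 3 the ratio was 360 (64.4 to 14200) for Bmp4 and 85.5 (29.1 to 416) for P4ha3. Without adult NSC 3 it was 481 (86.2 to 19000) for Prss22, while Bmp4 had no adult counts and was at least 159-fold lower. Without adult NSC 2 it was 371 (66.4 to 14700) for P4ha3. Without postnatal NSC 3, Fa2h fell by 5.91, Bgn by 5.88 and Veph1 by 5.78 on the log2 scale, in place of 6.83, 6.51 and 6.50. Without postnatal NSC 4, Thbd rose by 4.98 in place of 4.28. Scaling by library size alone moved the median log2 fold change of all genes to −0.12.

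**Figure D3:**
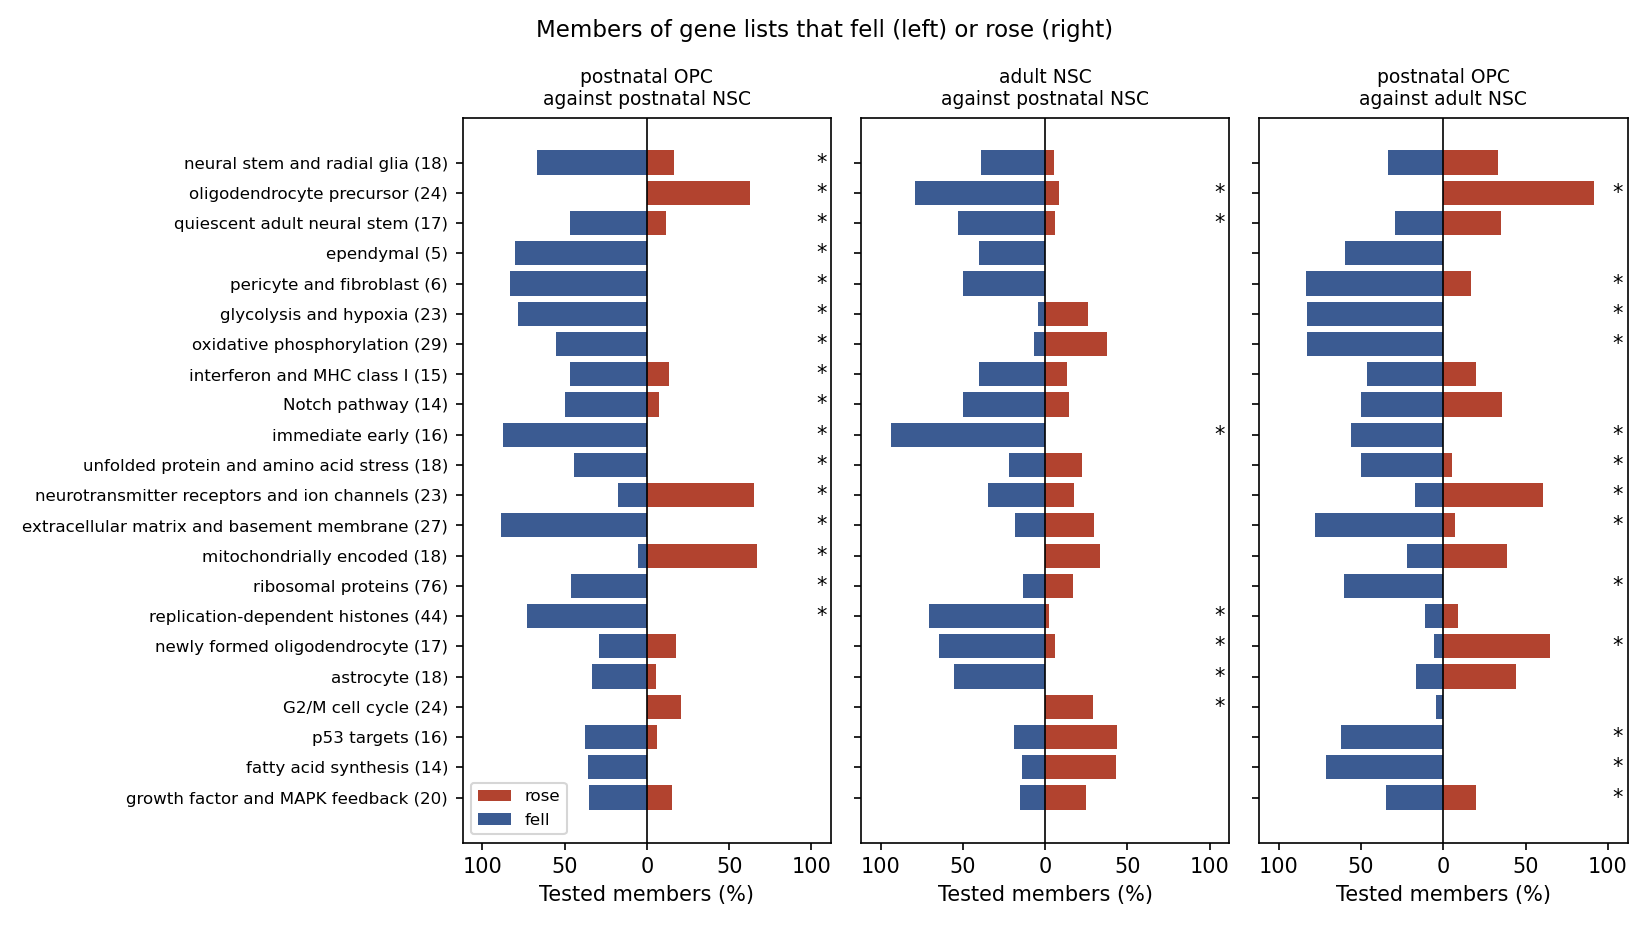
For each gene list called by camera in at least 1 comparison (y axis, number of tested genes in parentheses), the bars give the percent of tested genes (x axis) that fell (left) or rose (right) at an edgeR quasi-likelihood adjusted p under 0.05, and a star marks a camera adjusted p under 0.05. In the oligodendrocyte precursor list, 22 of 24 genes rose in postnatal OPC against adult NSC and 19 of 24 fell in adult against postnatal NSC.

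The remaining pair, postnatal OPC against adult NSC, differed in age, cell type and medium together but had similar depth. Pdgfra was 117-fold higher in OPC (1433 ± 710 against 12.2 ± 2.99 CPM, n = 4 each), and Sox10 was 15.4-fold higher. Cspg4 rose 4.36-fold and Sox2 1.57-fold. Dcx rose by 6.30 ± 0.67 on the log2 scale, or by 5.71 without postnatal OPC 2. Rph3a was at 93.9 ± 20.7 CPM in OPC and 0.242 ± 0.0907 CPM in adult neurospheres (387-fold). Nes fell 2.78-fold and Egfr 2.57-fold in OPC, while Gfap (22.9 ± 13.0 and 17.03 ± 6.70 CPM) and Mki67 (457 ± 141 and 599.9 ± 35.5 CPM) did not pass the test. In edgeR's quasi-likelihood test 4242 genes were higher and 3992 lower in OPC, of which 2111 and 1547 changed by at least 1 on the log2 scale.

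Of the 24 oligodendrocyte precursor genes, 22 rose and none fell, also adjusted over the list alone (camera adjusted p = 3.67e-20, and 0.0578 with an estimated correlation). Cacng4 rose by 2.71 ± 0.10, Cspg5 by 3.00 ± 0.12 and Matn4 by 8.94 ± 0.52. Of 17 newly formed oligodendrocyte genes, 11 rose and 1 (Nkx6-2) fell, or 12 and 1 adjusted over the list alone (camera adjusted p = 0.00961, and 0.76 with an estimated correlation). The transcription factor gene Zfp488 was 13.7-fold and the kinase gene Fyn 1.43-fold higher. In the mature oligodendrocyte and myelin list 7 of 15 genes rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.548). Mbp rose 5.29-fold (1.48 ± 0.682 to 7.85 ± 2.595 CPM). Neurotransmitter receptor and ion channel genes rose in 14 and fell in 4 of 23 cases, also adjusted over the list alone (camera adjusted p = 2.46e-06, and 0.012 with an estimated correlation). Gria2 was 5.84-fold and the NMDA receptor gene Grin3a 5.36-fold higher, and the NMDA receptor gene Grin2a and Gria1 lower. Among 14 transit-amplifying progenitor genes, 8 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.0892).

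Extracellular matrix genes fell in 21 of 27 cases with 2 rises, also adjusted over the list alone (camera adjusted p = 7.32e-15, and 0.131 with an estimated correlation). Tnc was 86.4-fold lower in OPC (45.3 ± 4.52 CPM in OPC), the perlecan gene Hspg2 12.2-fold lower, and Sparcl1 and Timp3 rose. Of 6 pericyte and fibroblast genes, 5 fell and 1 (Pdgfrb) rose, likewise adjusted over the list alone (camera adjusted p = 0.023, and 0.682 with an estimated correlation). The rise of Pdgfrb, a pericyte receptor gene, was 1.46 without postnatal OPC 2 in place of 3.32 ± 1.11 and did not pass (edgeR quasi-likelihood adjusted p of 0.192). Without adult NSC 1, 2 or 3 it did not pass either (edgeR quasi-likelihood adjusted p of 0.0584 to 0.0659, and 0.0143 to 0.192 over all edgeR settings). Of 23 glycolysis and hypoxia genes, 19 fell, also adjusted over the list alone (camera adjusted p = 2.26e-06, and 0.701 with an estimated correlation). The phosphofructokinase gene Pfkp was 6.43-fold and the aldolase gene Aldoa 3.46-fold lower. Oxidative phosphorylation genes fell in 24 of 29 cases, or 25 adjusted over the list alone (camera adjusted p = 4.16e-05, and 0.76 with an estimated correlation). The ATP synthase gene Atp5b was at 997 ± 108 and 1713 ± 31.5 CPM. Ribosomal protein genes fell in 46 of 76 cases, also adjusted over the list alone (camera adjusted p = 8.43e-05, and 0.883 with an estimated correlation). Rpl35a was 2.24-fold lower. Among 14 fatty acid synthesis genes, 10 fell and none rose, or 10 and 1 adjusted over the list alone (camera adjusted p = 0.0237, and 0.76 with an estimated correlation). Without both libraries with low G1/S genes the camera adjusted p was 0.0638 (0.00805 to 0.76 over all camera settings). The lipogenic transcription factor gene Srebf1 was 1.81-fold and the desaturase gene Scd1 1.68-fold lower. Of 18 unfolded protein and amino acid stress genes, 9 fell and 1 (Sdf2l1) rose, or 11 and 1 adjusted over the list alone (camera adjusted p = 0.0269, and 0.682 with an estimated correlation). That camera adjusted p was 0.0684 without those 2 libraries (0.0215 to 0.682 over all camera settings). The disulfide isomerase gene Pdia4 was 1.67-fold lower.

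Of 16 p53 target genes, 10 fell and none rose in OPC against adult NSC, or 13 adjusted over the list alone (camera adjusted p = 0.00259, and 0.682 with an estimated correlation). The cell cycle inhibitor gene Cdkn1a was at 42.3 ± 11.6 CPM in OPC and 367 ± 25.1 CPM in adult NSC (8.67-fold lower), and the p53 regulator gene Mdm2 was 1.59-fold lower. Of 20 growth factor and MAPK feedback genes, 7 fell and 4 rose, or 8 and 4 adjusted over the list alone (camera adjusted p = 0.0351, and 0.76 with an estimated correlation). Over all 16135 genes tested, 3992 fell and 4242 rose, shares not far from those of this list. Leaving out both libraries with low G1/S genes gave a camera adjusted p of 0.062 (0.017 to 0.76 over all camera settings). The ephrin receptor gene Epha2 fell 44.8-fold, and the transcription factor gene Etv1 and Il17rd rose 1.68-fold and 1.89-fold. Immediate early genes fell in 9 of 16 cases with no rise, or 10 adjusted over the list alone (camera adjusted p = 0.00881, and 0.76 with an estimated correlation). Jun was 3.74-fold and Klf4 14.3-fold lower. The camera adjusted p of the G1/S list was 0.47.

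Gpr17 was 196-fold higher in OPC (973 ± 1203 against 4.93 ± 1.73 CPM), a log2 rise of 7.62 that was 6.24 without postnatal OPC 2. Irx1, an Iroquois homeobox gene, was 209-fold higher in OPC (12.5 ± 10.6 CPM in OPC), a log2 rise of 7.70 that was 6.92 without postnatal OPC 2. With no counts in adult NSC, Rbpjl was at least 285-fold higher. It overlaps Matn4 on the other strand, so that their reads could not be told apart without strand. Gpr149, with 2 adult counts, had a ratio of 293 (95% counting interval 80.7 to 2420), the acid-sensing channel gene Asic4, with 3, a ratio of 159 (54.2 to 774), and P4ha3, with 3, a ratio of 166 (56.4 to 807). Without postnatal OPC 2 the ratio was 173 (47.4 to 1430) for Gpr149 and 97.5 (32.9 to 476) for Asic4. Without adult NSC 3 or 4 that of Gpr149 was 441 (78.9 to 17400) or 453 (81.1 to 17900), and without adult NSC 2 that of P4ha3 was 363 (64.9 to 14400). Large falls included Rab26 (326-fold), Anxa3 (267-fold), Tm4sf1 (217-fold), Rab3b (206-fold), the angiopoietin gene Angpt2 (184-fold), Fam110c (162-fold) and Thbs2 (146-fold). All 5 OPC counts of Fam110c were in postnatal OPC 3, and without that library it was at least 224-fold lower. In OPC, Tmc3 had 1 count (ratio 858 in favour of adult NSC, 154 to 33900), the ligand gene Tnfsf18 had 1 (ratio 461, 82.2 to 18200) and the meiotic cohesin gene Rec8 had 2 (ratio 330, 90.8 to 2730). Tmc3 had no OPC counts without postnatal OPC 3 (at least 226-fold lower), nor had Tnfsf18 and Rec8 without postnatal OPC 4 (at least 115-fold and 164-fold lower). The protein-coding gene Anxa3 (ENSMUSG00000029484.12) lies on chromosome 5 from 96793339 to 96845966 (GRCm38), Angpt2 (ENSMUSG00000031465.6) on chromosome 8 from 18690263 to 18741562 within Mcph1 on the other strand, and Thbs2 (ENSMUSG00000023885.9) on chromosome 17 from 14665500 to 14694235. The calls for Olig1 (0.52 ± 0.18) and Olig2 (0.53 ± 0.19) were lost when postnatal OPC 2 or any of adult NSC 2, 3 and 4 was left out, and that of Olig2 also without adult NSC 1. Without these libraries the edgeR quasi-likelihood adjusted p was 0.0605 to 0.0854 for Olig1 and 0.0613 to 0.0954 for Olig2 (0.00479 to 0.0854 and 0.00361 to 0.0992 over all edgeR settings).

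**Figure D4:**
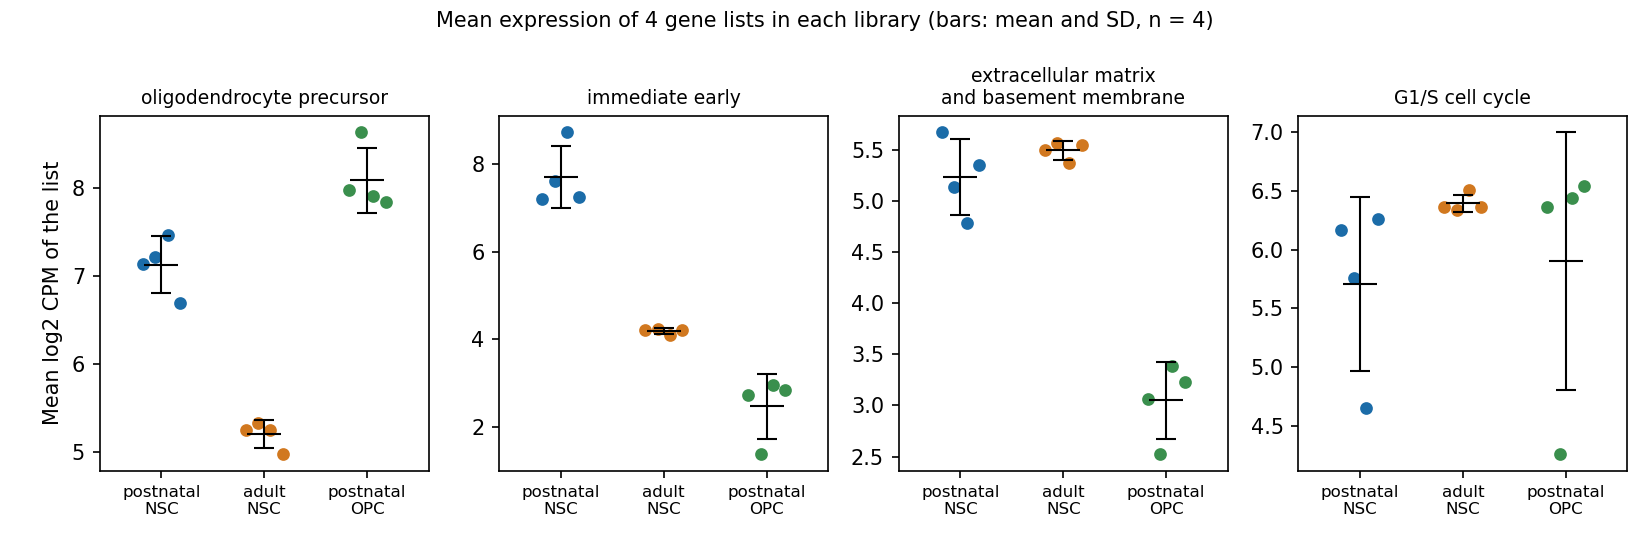
Mean log2 CPM (y axis) of the genes of 4 lists in each library, with 1 point per library, black bars for mean and SD of 4 libraries, and the 3 groups along the x axis. Immediate early genes averaged 7.21 to 8.74 in postnatal NSC libraries, 4.10 to 4.24 in adult NSC and 1.37 to 2.95 in postnatal OPC, and G1/S genes were lowest in postnatal NSC 3 and postnatal OPC 2.

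Each group also had genes that set it apart from both others in edgeR's quasi-likelihood test. Postnatal OPC had 1779 genes higher and 1994 lower than in both other groups, adult NSC 2054 and 2624, and postnatal NSC 1512 and 1738. Pdgfra, Cspg4 and Rph3a were among those highest in OPC, Rab26, Rab3b and Tnc among those highest in adult NSC, and Fos, Fosb and Junb among those highest in postnatal NSC. Against postnatal NSC, 1738 genes were higher and 1512 lower in both OPC and adult NSC, where independent lists would share 910 and 1022, and 1098 genes changed in opposite directions. With the postnatal NSC libraries split between the comparisons, the medians over 6 arrangements were 1189 and 1010 genes, against 616 and 697 for independent lists, and 784 genes (552 to 1883) changed in opposite directions. Simulated unchanged groups shared no calls, and their log2 fold changes had a correlation across genes of 0.459 and a covariance of 0.042, against 0.197 and 0.219 observed. The observed covariance exceeded the simulated one by 0.177. The simulation gave all groups the same spread per gene. Postnatal NSC libraries differed more from each other (median Spearman correlation 0.982) than adult NSC libraries (0.996). The simulated covariance may therefore be too small and this excess too large. With split controls, whose comparisons share no postnatal NSC library, the correlation was −0.038 to 0.25 and the covariance −0.051 to 0.266. The simulated covariance came from shared controls, so it is no reference for the split ones. Part of the excess may come from the shared libraries.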

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

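Groups of 4 libraries were searched for 1 library far from the other 3, by Dixon's ratio above its 95% critical value. Of 183 groups of values, 20 had such a library, where chance flags about 1 in 20 groups, or 9.2 here. The tests in this part were planned, but which values to follow up was decided after they were seen, and no explanation was tested for any of them.

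Postnatal OPC 2 accounted for 9 of the 20 values. Its G1/S genes were at a mean of 4.259 log2 CPM (6.366 to 6.542 in the other 3), cholesterol synthesis genes at 6.03 (7.117 to 7.336), MAPK feedback genes at 4.079 (5.162 to 5.385) and immediate early genes at 1.373 (2.727 to 2.95). In the same library, log2 CPM was 11.285 for Pdgfra (10.011 to 10.167 in the others), 10.174 for Olig2 (9.64 to 9.692), 8.832 for Nes (9.669 to 9.742), 7.011 for Egfr (8.276 to 8.351) and 7.955 for Mki67 (8.989 to 9.105).

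Postnatal NSC 2 had the highest total of its group, 54.8 (in units of 1e6 counts) against 38.9 to 39.5. In postnatal NSC 4, pericyte and fibroblast genes were at a mean of 2.091 log2 CPM (3.11 to 3.189 in the others) and imprinted growth genes at 4.883 (5.157 to 5.205). In postnatal NSC 1, inflammatory and complement genes were at 1.833 (1.174 to 1.21) and hedgehog pathway genes at 4.924 (4.649 to 4.694). In adult NSC 1, interferon and MHC class I genes were at 2.743 (2.53 to 2.55) and sex-linked genes at −0.999 (3.587 to 3.971). The sex-linked list averages Xist with Y-linked genes. In adult NSC 1 Xist was at 1097 CPM and Ddx3y at 0.0 CPM. The other adult libraries had Xist at 0.05 to 0.22 CPM and Ddx3y at 37.3 to 47.11 CPM, so the sex-linked flag restates these levels. Adult NSC 3 had G1/S genes at 6.504 (6.34 to 6.366), Notch pathway genes at 5.028 (5.119 to 5.131) and immediate early genes at 4.097 (4.223 to 4.238). In adult NSC 4, Sox2 was at 7.628 (7.76 to 7.775).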

How the results depend on the processing

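Tests chosen after the results were seen were the covariate for Y-linked expression, the removal of both libraries with low G1/S genes or of genes with shared stretches, for gene lists also thinning, and for results other than the genes of each comparison the removal of single libraries; the others were planned. Counts of genes higher and lower in each comparison stayed within 1.5 times of the reported ones in every setting without a fold minimum. With a log2 fold change of at least 1 they were 1127 and 1566 for postnatal OPC against postnatal NSC, 1060 and 2170 for adult against postnatal NSC, and 2111 and 1547 for postnatal OPC against adult NSC, fewer by construction. Without each library in turn they were 2941 to 3928 and 3184 to 4258, 3167 to 3928 and 3888 to 5041, and 3681 to 4151 and 3507 to 3825. Lists called, 16, 7 and 13 with the preset correlation, numbered 1, 0 and 1 by camera with an estimated correlation and 26, 28 and 25 by fry. Both camera runs differed only in the correlation used. Unlike camera, fry does not compare a list with the other genes, and 45.1% to 53.1% of all genes tested were called. The numbers by fry are thus no separate support for the lists. With the replicate block 11 lists were called in adult against postnatal NSC, and genes higher and lower were 3423 and 3388, 3896 and 4147, and 3959 and 3859. Replicate numbers did not pair the libraries, with correlations of deviations between the same numbers of −0.36 to 0.32. Over all genes the first principal component held 53.1% of the variance. With the Y-linked covariate Xist turned to a log2 rise of 5.243 in postnatal OPC against adult NSC (adjusted p 0.0178, edgeR quasi-likelihood test), the 1 reversal among named genes, whose cause was not tested. Scaling by library size alone gave 3333 genes higher and 5286 lower in adult against postnatal NSC. Thinned to the smallest total, the counts were 3411 and 3608, 3845 and 4420, and 4127 and 3881. With only the 8 libraries compared they were 2843 and 2856, 4087 and 4562, and 4611 and 4355. For postnatal OPC against postnatal NSC, 21 of 222 named genes lost their call in that setting. The fit to all 12 libraries, which pools the spread of the groups, thus called more genes there. The Y-linked covariate gave 2505 and 2552 in the same comparison.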

Other observations

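In adult against postnatal neurospheres, 10 of 18 imprinted growth genes fell and 4 rose, likewise adjusted over the list alone (camera adjusted p = 0.127). The noncoding RNA gene Meg3 was at 0.156 ± 0.0641 CPM in adult and 5.95 ± 2.94 CPM in postnatal NSC, and Cdkn1c, an inhibitor of cell cycle kinases, fell 6.8-fold. By contrast, Peg10 rose 3.64-fold and the receptor gene Igf2r 1.67-fold. Igf2bp3, an RNA-binding protein gene active in fetal growth, fell by 2.58 ± 0.10 on the log2 scale (65.1 ± 6.64 to 10.9 ± 0.271 CPM), with an edgeR quasi-likelihood adjusted p of 6.8e-09. Of 16 p53 target genes, 7 rose and 3 fell, likewise adjusted over the list alone (camera adjusted p = 0.148), with Zmat3 rising by 1.04 ± 0.17 and Cdkn1a by 1.11 ± 0.32. Of 9 ventral telencephalic genes, 5 fell and 2 rose, likewise adjusted over the list alone (camera adjusted p = 0.405). The ventral transcription factor gene Nkx2-1 had 187 counts in postnatal NSC and none in adult NSC, at least 26.9-fold lower, or at least 15.6-fold without postnatal NSC 1.

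The patterns weighed below are hypotheses found and tested on the same data. Chosen after the results were seen were the tests of S phase, of other RNAs without a poly(A) tail, of batch, of age or cell type alone, and of pseudogene levels in OPC; the other tests were written down first.

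Immediate early genes were higher in postnatal NSC than in both other groups. Their median log2 fold change in adult against postnatal NSC was −3.266 with Y-linked expression as a covariate, which argues against fewer male cells as the whole cause. With all libraries thinned to the smallest total it was −3.501. Thinning keeps each gene's share of a library on average, so it could hardly move this median and does not decide on depth. Handling or library batch cannot be told apart from the group, since no label gives a batch that holds libraries of more than 1 group, and the median of −3.496 is then also a gap between batches. Age alone would leave OPC, and cell type or medium alone adult NSC, at the level of postnatal NSC, but the medians against postnatal NSC were −4.783 (SD 2.777) and −3.496 (SD 2.31). The pattern was picked after these genes were seen to be higher than in both other groups. These medians therefore restate it and are no separate test. Neither age alone nor cell type or medium alone would give them, while both together stay open.

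Replication-dependent histone transcripts were also higher in postnatal NSC, with a median log2 fold change of −1.467 in adult NSC. More cells in S phase, as the whole cause, would lower G1/S genes in adult NSC by about as much, but their median was 0.49 (SD of 0.362 over 24 genes). Without postnatal NSC 3 and postnatal OPC 2 it was 0.247 (SD 0.359, histones −1.385), which also argues against S phase as the whole cause. After thinning the median was −1.587, which does not decide on depth, since thinning keeps each gene's share of a library. The medians of −1.426 (SD 0.643) in OPC and −1.467 (SD 0.866) in adult NSC restate the pattern and are no separate test. Neither age alone nor cell type or medium alone would give both. A batch that kept more RNA without a poly(A) tail may contribute and stays open, since 19 other such RNAs had a median of −0.433 with an SD of 1.24 between genes. Many of the histone genes share most of their stretches with other genes, such as Hist1h2bq (97.3%) and Hist1h3h (93.9%). Others share few, such as Hist1h1c (8.5%). The treatment of shared reads was not given, so the counts of such histone genes may not be independent. The histone medians were not computed without them.

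Of 1475 processed pseudogenes tested, 106 fell by more than 2 on the log2 scale in adult against postnatal NSC and nearly as many rose by more than 2. The median of all was 0.033. Reads shared with near-identical genes were argued against as the whole cause. Of the fallen pseudogenes 47.2% shared at least 50% of their stretches, against 59.8% of the others (two-sided Fisher's exact test, p = 0.0137). For the 50 fallen pseudogenes above that share such reads stay open, since their treatment was not given. The 11 distinct parent genes that could be named had a median change of 0.249 (SD 0.537). Of the 100 fallen pseudogenes still tested after thinning, 98.0% remained more than 2 lower. Thinning keeps each gene's share of a library, so this does not decide on depth. In postnatal OPC, 83.0% of the fallen pseudogenes lay within 1 of postnatal NSC on the log2 scale, against 47.6% of 607 protein-coding genes that fell as much (two-sided Fisher's exact test, p = 3.88e-12). Postnatal and adult cultures from animals that differ in these fallen pseudogenes would give this, while age stays open. A batch that followed the groups, which no label names, was not tested. Of the pseudogenes that rose, 92 were also more than 1 higher in OPC than in postnatal NSC. Their median was 0.112 CPM in postnatal NSC, 0.851 CPM in adult NSC and 0.757 CPM in OPC. OPC thus lay near adult NSC, which postnatal and adult animals that differ in these pseudogenes would not give. The risen set decides no cause by itself, since both comparisons share the postnatal NSC libraries, where its levels were low. Pseudogenes are not independent of each other, so both Fisher p values are likely too small.

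Other splits of the libraries were tested as well. For genes changed, 1.0 of 35 splits, the real one, gave as many in each comparison. For postnatal OPC against postnatal NSC there were 7276 against a highest other of 1111. Adult against postnatal NSC gave 8569 against 1, and postnatal OPC against adult NSC 8234 against 0. A share of 1 in 35 is the smallest these splits can give. Splits that mix the groups put the gap between groups into the spread, and so call few genes. The real grouping thus gave the most calls, but the splits cannot exclude chance or a batch that followed the groups. For the number of lists called, 10, 27 and 15 of 35 splits gave as many. Some splits kept most of a group together, such as adult NSC 1, 3 and 4 with postnatal OPC 4, so part of the real gap remained in them. These numbers therefore do not decide on chance, which cannot be excluded. The lists numbered 16, 7 and 13, against highest others of 24, 20 and 19. Of 100 drawn splits into 3 groups, 1.0, the real one, gave as many genes that were highest in 1 group (5345 against 1153). The limit of splits that mix the groups holds there too. The splits do not test whether changes agree between the comparisons with postnatal NSC, which share libraries.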
